A study of Mus musculus with 4 samples.

How the data were processed

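Mouse embryonic stem cells of the D3 line were grown attached to the dish or in suspension, and total RNA of each culture was measured on 4 Agilent two-colour arrays, 2 per culture. Per the labels' protocols, the cells' RNA carried Cy3 and a pool of RNA from cultured mouse cell lines, the same on every array, carried Cy5. No dye swap was recorded, so any dye bias of a probe stays in its ratio to the pool, while it cancels in the difference between cultures as far as it is equal on all arrays. Samples were grouped by the culture named in the labels. The labels number the replicates 1 and 2 in each group and do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

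The spot intensities were deposited by the authors as scanner output of Feature Extraction, version 7.5.1 per the file headers. Per the file headers, the multiple used to call a spot well above background was 2.6. The processed signals, also intensities, had been background-subtracted and dye-normalized, per the file headers. The log10 ratio in the deposited scanner output is Cy5 over Cy3. Per the submitters' processing notes the tool was Agilent Feature Extraction. The submitters' value table held 25674 features on a log10 scale, with column medians of 3.00, 2.99, 3.00 and 3.01 for attached 1, attached 2, suspension 1 and suspension 2. For 88.6% of its features, the table's value plus the scanner's log10 ratio was the same on all 4 arrays within 0.001. The table therefore runs as Cy3 over Cy5, with a constant per feature that correlated with the mean log10 Cy5 signal across features (Pearson r = 0.992, features not being independent replicates). How its features were chosen and why the remaining values differ is not given in the sources used here.

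Each array held 44290 spots, of which 2256 were controls. Mean signals were corrected against the local background medians by normexp with an offset of 50, and loess was fitted within each array with control and outlier spots at weight 0. Ratios were turned to log2 of Cy3 over Cy5, so that higher means more RNA in the cells. The spots of a probe were averaged, giving 42006 probes. Probes with Cy3 well above background on at least 2 of the 4 arrays were kept (41352), 94 of these with an outlier flag on an array were left out, and 41258 were tested. The offset of 50 shrinks the fold changes of dim probes.

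The cultures were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Intervals are 95% confidence intervals of that fit. On simulated log ratios for the 41258 probes with 200 changed probes in each of 20 runs, the fit recovered 65.9% of the probes changed 2-fold and 91.2% of those changed 4-fold, and 1.90% of its calls were false. The simulation changed far fewer probes than were called in the data, and gave both cultures equal spread and independent errors. These shares therefore do not carry over to the calls in the data.

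Fixed before the data were examined were the test, the groups, 30 gene lists, the rule for naming genes and most of the alternatives. The files give probe identifiers and 60-base probe sequences and do not pair them with gene names, and the gene table used here holds names without sequences. The 30 lists and the interval for the pluripotency genes were therefore not analysed here, and choosing a probe per gene had no effect because every probe stood on its own. The rule named genes with the largest log2 fold change among those past the threshold with both suspension arrays beyond both attached arrays. Without names it was limited to 2 probes in each direction. The comparisons with the reference pool, including the class boundary of 4-fold, were added after the data were seen. Classes were tested with limma's camera, which compares a class with the other probes, at a preset correlation of 0.01 and with an estimated correlation. They were also tested with fry, which tests a class against no change.

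Alternatives changed the background correction, the normalization, the channel used, the filter on dim probes, the variance model, the threshold and the samples. Every array was on its own slide and the headers give no scan date, so neither was used as a block. For arrays, the number of samples limits the precision.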

Results

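The study asked whether mouse embryonic stem cells stay undifferentiated when grown in suspension in a defined medium without serum or feeder cells. Embryonic stem cells are pluripotent cells derived from the early embryo, and D3 is an established line of them. RNA from attached cultures (n = 2) and suspension cultures (n = 2) was hybridised against a common reference pool of mouse cell lines. Each value below is a log2 ratio of the cells' signal to that of the pool, and each difference is suspension minus attached. The files do not pair probes with genes, so pluripotency and differentiation genes could not be looked up, and probes are given by identifier and sequence.

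Median net Cy3 intensity, the cells' channel, was 85.3 and 85.9 on the attached arrays and 136.8 and 123.3 on the suspension arrays. Median net Cy5 intensity, the pool's channel, lay between 264.5 and 285.9. Cy3 was well above background at 97.3% and 98.3% of spots in the attached arrays and at 97.7% and 96.0% in the suspension arrays. Log ratios of the attached pair correlated with r = 0.991 across probes and those of the suspension pair with r = 0.970, while the 4 pairs that crossed cultures gave r from 0.875 to 0.893. Probes are not independent replicates in these correlations. The spread between replicates was wider in suspension (SD 0.14 on the log2 scale) than in attached culture (SD 0.08).

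Suspension and attached cells differed at 9765 of 41258 probes, or 23.7%, of which 4659 rose and 5106 fell in suspension. With median centring in place of loess the balance turned, with 6224 higher and 5023 lower. Of 286 tested probes saturated in Cy5 on any array, 88 rose and 7 fell, and of 95 saturated in Cy3, 11 rose and 1 fell. Since most of the saturated probes that changed rose, they cannot account for the excess of falls in the main count. No alternative left saturated probes out, so their part in the larger changes was not tested. Most of the 9765 changes were small. The median size among the changed probes was 1.40-fold, and 6276 of them changed by less than 1.5-fold. Among the larger changes, rises outnumbered falls. At least 2-fold changes were found for 641 probes that rose and 395 that fell, and at least 4-fold changes for 98 that rose and 23 that fell. These counts moved with the processing. By at least 2-fold, 185 rose and 91 fell without background subtraction, and 842 and 524 with an offset of 16. With the processed signals, which differ in both background correction and dye normalization, 997 rose and 666 fell. At 4-fold the counts ran from 18 and 4 without background subtraction to 240 and 81 with Cy3 alone scaled to the 75th percentile. In that last setting 1503 of the 1647 changed probes reached 2-fold, so most changes were not small there. These calls came from limma with Benjamini-Hochberg adjustment. The count was lower with fewer attached arrays. It was 1340 without attached replicate 1 and 1481 without attached replicate 2, in fits where the lone attached array is assumed to vary like the suspension pair. Rises of at least 2-fold then numbered 330 and 348, and falls 330 and 350.

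**Figure D1:**
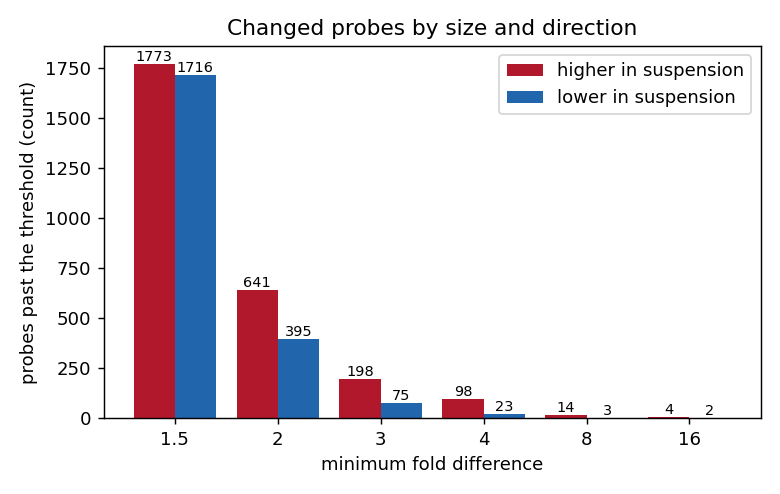
Number of probes past the threshold (y axis, count) whose difference reached at least the fold given on the x axis, for probes higher (red) and lower (blue) in suspension. At 1.5-fold the bars stand at 1773 and 1716, and at 4-fold at 98 and 23.

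Among the probes that rose most was Z00035970-1, with the sequence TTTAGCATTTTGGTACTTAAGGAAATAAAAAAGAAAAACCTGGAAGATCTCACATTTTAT. Its log2 ratio was -0.92 ± 0.08 (SD, n = 2) in attached and 3.66 ± 0.32 (SD, n = 2) in suspension cells. The log2 difference was 4.58 (SE 0.15, limma adjusted p = 0.000121). Its Cy3 signal was well above background on only 1 of the 2 attached arrays, so its fold change is poorly fixed. The log2 difference was 2.79 without background subtraction and 6.74 with Cy3 alone scaled to the 75th percentile. Probe Z00023088-1, with the sequence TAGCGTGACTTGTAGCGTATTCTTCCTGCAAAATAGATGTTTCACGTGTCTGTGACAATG, went from 0.23 ± 0.01 to 4.56 ± 0.13 (SD, n = 2 each), a log2 difference of 4.34 (SE 0.08, limma adjusted p = 3.95e-05).

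Among the probes that fell most was Z00034666-1, with the sequence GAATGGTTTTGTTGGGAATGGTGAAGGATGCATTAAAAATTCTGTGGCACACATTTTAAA. Its log2 ratio was 4.74 ± 0.08 (SD, n = 2) in attached cells and 0.02 ± 0.10 (SD, n = 2) in suspension cells, a difference of -4.73 (SE 0.08, limma adjusted p = 3.95e-05). Probe Z00005803-1, with the sequence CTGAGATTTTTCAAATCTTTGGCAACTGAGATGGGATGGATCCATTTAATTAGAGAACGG, went from 1.33 ± 0.06 to -2.70 ± 0.14 (SD, n = 2 each), a difference of -4.02 (SE 0.09, limma adjusted p = 4.18e-05). The fold changes of the 3 probes other than Z00035970-1 also moved with the processing. From no background subtraction to Cy3 alone scaled to the 75th percentile, the log2 difference ran from 3.58 to 6.10 at Z00023088-1, from -3.58 to -5.61 at Z00034666-1 and from -2.16 to -5.43 at Z00005803-1. None of these 4 probes was saturated in either channel on any of the 4 arrays, and the 3 others were well above background in Cy3 on all 4.

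**Figure D2:**
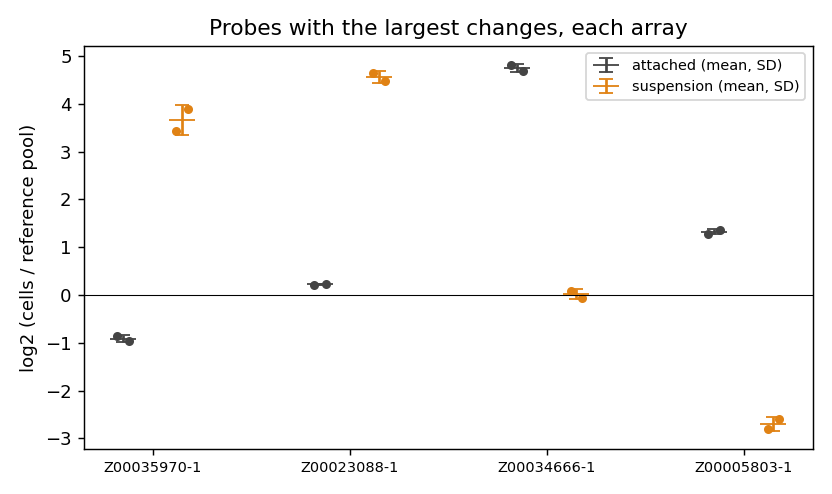
Log2 ratio of the cells to the reference pool (y axis) on each array for the 4 named probes (x axis), with points for arrays and bars for the mean and SD of 2 arrays in attached (grey) and suspension (orange) culture. At each probe the replicates lie close together compared with the distance between cultures, as at Z00034666-1, where the means are 4.74 and 0.02.

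The measured difference was also bounded at most probes. For 39170 probes, or 94.9%, the 95% interval of the difference lay within 2-fold in both directions, and for 533 it lay wholly beyond 2-fold. The share was 92.4% with an offset of 16, the other steps kept. It was 86.2% with the scanner software's processed signals, which differ in dye normalization as well, 84.7% with the submitters' values and 65.9% with Cy3 alone scaled to the 75th percentile.

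Against the reference pool, 989 probes were at least 4-fold higher in attached cells. In suspension 572 of them, or 57.8%, were still at least 4-fold above the pool, and 96.0% were at least 2-fold above it. Selecting probes in a culture lowers the share in the other by itself. In the reverse direction, of 862 probes at least 4-fold above the pool in suspension, 66.4% were so in attached cells. The shares between replicates compare single arrays, not means. They were 94.0% from attached 1 to attached 2 and 77.6% from suspension 1 to suspension 2. Single arrays across cultures gave 59.8% from attached 1 to suspension 1 and 55.5% from attached 2 to suspension 2. Of 590 probes at least 4-fold below the pool in attached cells, 77.8% were so in suspension. For single arrays this share was 78.5% from attached 1 to suspension 1 and 76.2% from attached 2 to suspension 2. Replicates gave 97.3% from attached 1 to attached 2 and 92.0% from suspension 1 to suspension 2. These shares have no test, and the 57.8% moved between 44.3% and 70.7% with the normalization.

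**Figure D3:**
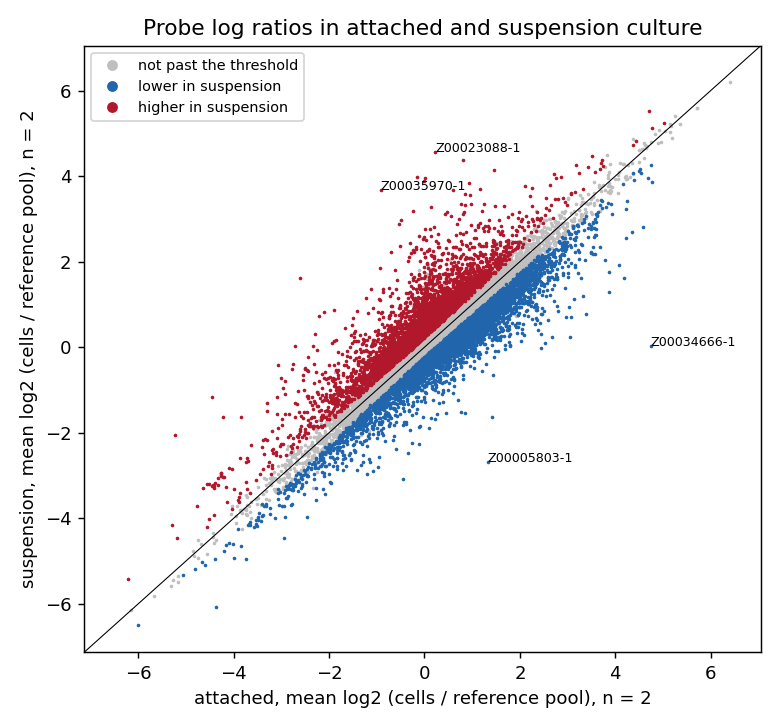
Mean log2 ratio of the cells to the reference pool in attached (x axis) and suspension (y axis) culture, 2 arrays each, for the 41258 tested probes, with the line of equal values. Red points are the 4659 probes that rose in suspension, blue points the 5106 that fell, and grey points did not pass the threshold.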

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

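In this part, the tests of array brightness, of a single suspension array and of the Pro25G probes were chosen after the result was seen. The GC correction, too, was chosen after seeing the data. Some of the manufacturer's control probes, which no comparison in the report used, carried a signal far above the negative controls. The 37 probes eQC 00 to 36 had log2 ratios of 3.51 and 3.66 on the attached arrays and 3.22 and 3.38 on the suspension arrays, a difference of -0.28. The dimmer control families did not show it, with differences of -0.02 for eQC 37 to 42 and -0.03 for E1A. Raw net Cy3 at eQC 00 to 36 differed little between cultures (suspension over attached 1.06), whereas at the probes for mouse RNA it was 1.52 times as bright in suspension. Brighter Cy3 labelling of the suspension RNA, which loess scales down together with the controls, is consistent with the values at eQC 00 to 36. For the Pro25G controls, whose log2 ratio also fell by 0.33, raw Cy3 was 1.22 times as bright in suspension. That is beyond the 1.2-fold limit set for the test, so the question stays open for them.

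The number of changed probes, 9765, was set against 3 technical explanations. If the brighter Cy3 of the suspension arrays had made the calls through dim probes, few bright probes would pass, but 43.9% of the brightest 10% did. Of the dimmest 10%, 4.39% passed. Because the offset shrinks differences at dim probes, fewer calls were bound to arise there. The result therefore speaks only against calls made through dim probes alone, and an effect of brightness on bright probes was not tested. Removing each array's trend on probe GC content kept 96.4% of the calls with the same sign, which argues against GC content as the whole cause. Probes at least 2-fold apart between an attached and a suspension array had the same sign in the remaining pair, which shares no array with it, in at least 97.3% of cases, and the differences of such pairs correlated across all probes (r from 0.827 to 0.838), which argues against a single aberrant suspension array as the whole cause. Differences in handling between the cultures cannot be told apart from the culture itself with these samples, since the labels give no batch, and the difference in culture stays an untested biological explanation.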

How the results depend on the processing

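The GC correction, the restriction to the submitters' features and the pool classes were chosen after seeing the data. The count of 9765 changed probes stayed within 1.5 times under 13 of 17 alternatives that kept all arrays (6667 to 11247). It was 3935 with Cy3 alone after quantile normalization (1979 higher, 1956 lower) and 1647 with Cy3 alone scaled to the 75th percentile (822 and 825). When 2-fold was required as well it was 1036 (641 and 395). The submitters' values gave 5087 (2345 and 2742), but of only 25291 tested probes against 41258 in the main fit. Of the main calls, 7284 were at probes in the submitters' table. Scanner values on the submitters' probes gave 7596 of 25238. That count was also set against 9765 as it stands, without allowing for the smaller set of probes. Without 1 array the count ran from 1340 to 12630, with 577 to 6122 higher and 763 to 6585 lower. Each such fit has a lone array in a group and takes its spread from the other pair. Otherwise the cause was not tested.

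With the replicate number as a block the count was 9278. Same-numbered deviations correlated with r = -0.0388 across probes over only 2 pairs, too few to tell, so the numbers were not taken to pair the samples. The named probes kept direction and threshold in all 78 values, which is little support because they were picked as the largest changes on these same arrays. Z00035970-1 was not tested where Cy3 had to be well above background on all 4 arrays. Rises of at least 4-fold outnumbered falls in 20 of 20 alternatives, and rises of at least 2-fold in 18, the exceptions being without attached replicate 1 (330 each) and 2 (348 against 350).

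For probes at least 4-fold above the pool, the median shift against all probes turned from negative to 0.035 without background subtraction and 0.034 with median centring. For those below it, it turned to 0.021 with median centring, 0.24 with scaling between arrays, and 0.033 or 0.075 with Cy3 alone by quantiles or percentile. For the first class median centring is weighed under the other observations, and the cause of the other turns was not tested. Quantile normalization of mean intensities cannot move a ratio and is counted nowhere here. Scan date, slide and gene list tests were not run. Dim probes are limited by signal over background.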

Other observations

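The pool classes and the test of within-array normalisation were chosen after the data were seen. Among 808 probes at least 4-fold above the reference pool on the mean of all 4 arrays, 275 fell and 126 rose in suspension, with a median log2 difference of -0.13. Scaling between arrays gave 494 lower and 64 higher (shift relative to all probes -0.47), and median centring 183 lower and 173 higher. With limma's camera the class shifted down against the other probes at p = 0.0134 with the preset correlation, but p = 0.489 with an estimated correlation, and limma's fry, which tests against no change, gave p = 0.0689. Without suspension replicate 2 the shift relative to all probes was -0.06 (camera p = 0.271 with the preset correlation). In the main comparison the fall was not particular to this class. Among probes at least 4-fold below the pool 202 fell and 121 rose (shift -0.12, limma's camera p = 0.0439 with the preset and 0.394 with an estimated correlation, limma's fry against no change p = 0.0312). That depended on the setting. At these probes the shift was -0.02 with processed signals (104 higher, 96 lower) and -0.04 with an offset of 16 (124 higher, 134 lower). Cy3 alone by quantiles gave 0.03 (76 higher, 43 lower), while no background subtraction gave -0.22 (44 higher, 250 lower). The hypothesis that transcripts enriched in these cells over the pool tended to be lower in suspension was then set against 4 technical explanations. Cy3 alone gave a median relative to all probes of -0.11 by quantiles (camera p = 0.0316 with the preset correlation). Scaled to the 75th percentile, it gave -0.09 (camera p = 0.133 with the preset correlation). These values argue against the reference channel as the whole cause, though the 75th percentile gave weaker evidence of a shift. The class median of -0.13 lay below 1000 sets matched on mean intensity, the lowest at -0.08. Loess had already removed each array's trend on mean intensity, so matched sets were bound to show little shift. The matching therefore cannot decide whether mean intensity plays a part. Matching on the mean of both channels left each channel unmatched, so intensity in a single channel was not tested. The offset as such does not account for the shift, since processed signals, which carry none, gave -0.13, and an offset of 16 gave -0.14. With median centring in place of loess, however, the shift was 0.034, and without background subtraction it was 0.035. The within-array normalisation or the background correction may therefore produce it, and no biological reading is supported.

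Probes with GC content above 60% fell more often than they rose, 16.2% against 3.57%, while at 30 to 35% GC 14.2% fell and 17.4% rose, and at 30% GC or less 14.7% fell and 13.6% rose. At the 7 probes printed on 5 spots each, the SD between spots of an array was 0.10 on the log2 scale. Of the tested probes, 253 were well above background in Cy3 on both attached arrays and on neither suspension array, but only 22 of them passed the threshold as lower. The opposite was seen at 45 probes, of which 10 passed as higher and 1 as lower.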
